A study of Mus musculus with 2 samples.

How the data were processed

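RNA of B cells from mouse peripheral lymph nodes was compared between wild-type C57BL/6J mice and mice with a targeted Ccr7 allele on a B6 background. Per the labels' protocols, cells were sorted by flow cytometry and their RNA was isolated without culture, 20 ng of total RNA per condition was amplified to aminoallyl cRNA, and the cRNA was labelled with Cy3 or Cy5. The series' design text describes 12 sorted samples, 6 of each genotype, whose RNA was combined in pools of 3. This gave 2 pools per genotype and 2 two-colour arrays, each of which held 1 wild-type and 1 knock-out pool. On array 1 the knock-out pool was labelled with Cy5, and on array 2 with Cy3. Each array is the unit of replication here, so n = 2.

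The spot intensity values were deposited as scanner output. Per the file headers and the submitters' processing notes, the authors quantified both arrays with Agilent Feature Extraction 9.5.3.1, which records the mean intensity of each spot and the median intensity of its local background in both colours. The headers name the mm8 build for probe positions, and both arrays lay on the same slide. The same files hold a log10 ratio of Cy5 over Cy3, which per the file headers was background-subtracted and dye-normalized by that program. The headers also record that each array was read at 2 scanner gains, and the brightest spots carry a flag for a value scaled up from the low-gain scan. This flag was set in at least 1 channel of 1958 spots on array 1 and 1703 spots on array 2. The deposited value table holds log2 ratios. Set against the scanner files with a tolerance of 0.001, it equalled the log ratio, turned to knock-out over wild-type, at 42512 of 43379 spots on array 1 and 42515 of 43379 on array 2. Each of the 867 and 864 other spots carried the low-gain flag. How those values were made is not given in the sources used here. The median of each column of that table was 0, and its scale and direction were settled by this comparison.

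From the intensity values, the background was corrected with normexp (offset 50), and each array's log2 ratios were normalized by loess (span 0.3, 4 iterations) with the 1639 control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots with a non-uniformity or population outlier flag were left out, and spots of the same probe were averaged. A probe was kept where the wild-type channel on both arrays, or the knock-out channel on both arrays, was well above background. Each gene was represented by its probe with the highest mean log2 intensity, which left 17684 genes. The offset shrinks ratios of dim probes towards 0.

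Of 41174 distinct probes, 24375 were named through the RefSeq accession in the file, 6301 through a current symbol and 2422 through an older synonym. The other 8076 kept the name in the file. Positions were used only as the files give them, on mm8.

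Ratios were fitted with lmFit and eBayes, with a design of +1 where the knock-out was Cy5 and -1 where it was Cy3. The coefficient is log2 knock-out over wild-type. A dye effect cancels in the mean of both orientations and stays in the residual, where it cannot be separated from the difference between pools. The fit has 1 residual degree of freedom per gene plus 6.19 prior degrees of freedom. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. The 20 gene lists were tested with camera (inter-gene correlation 0.01) where at least 5 members were measured, which held for 18, and adjusted over those 18. Camera with an estimated correlation and fry were the alternatives. With 1 residual degree of freedom, camera with an estimated correlation had a lowest unadjusted p of 0.0983 over the 18 lists. It could hardly pass any list, so a loss there does not by itself show correlation between members. The estimated correlation was 0.302 for type I interferon response, 0.181 for unfolded protein response and 0.153 for cell cycle. For these lists the fixed 0.01 can make the camera p too small. For the other lists past camera it was at most 0.011 (germinal centre). Genes within 10 Mb of Ccr7 on chromosome 11 were tested with camera and with Fisher's exact test.

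The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took Ccr7 and, among genes with a proper symbol past the threshold and in the same direction on both arrays, up to 15 of the largest rises and 15 of the largest falls. A direction with fewer than 10 was filled to 10, as far as possible, with genes at least 2-fold in the same direction on both arrays, in order of unadjusted p. From each list it took up to 4 members past the threshold, or the 2 with the largest absolute mean difference where none passed. Members past the threshold when adjusted over the list alone are named as such. The values of 1 gene that the rule takes are not reported here. A genotype not well above background on either array has only a bound: the mean of the brighter genotype against the higher of the dim signal and the lowest signal well above background, per channel after loess and Aquantile normalization.

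The alternatives were no background subtraction, an offset of 16, the scanner program's own log ratio, median centring, no within-array normalization, 2 other filters on dim probes, flagged spots kept, all probes, the mean of probes, an intensity trend with a robust prior, the deposited value table, separate channel fits, each array alone, and other thresholds and windows. An alternative without genes scaled up from the low-gain scan was added after the data were examined. The steps were tested on simulated data for the 17684 genes of this comparison with 100 genes changed 2-fold and 100 changed 4-fold. The fit called 69% of the 2-fold and 100% of the 4-fold genes, all in the right direction, with 8 false calls. The simulated noise was independent between genes, with variances drawn from the fitted prior. It held no disturbance of scaled-up spots and no dye effect of single genes. These rates therefore check the steps and do not give the power of the real arrays.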

Results

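Gene expression was measured in B cells sorted from peripheral lymph nodes of wild-type mice and of mice lacking a functional Ccr7 gene, which encodes a chemokine receptor that guides lymphocytes and dendritic cells into lymph nodes. The comparison addresses how B cells in these nodes differ when the receptor is missing. It rests on 2 arrays with swapped dyes, each with a separate pool of 3 RNA samples per genotype. On array 1, 68.2% of spots were well above background in Cy5 (knock-out) and 63.1% in Cy3 (wild-type). On array 2 these shares were 68.8% in Cy5 (wild-type) and 58.4% in Cy3 (knock-out). No spot was saturated. The number of arrays limits the precision of every value. The p-values and SE of the fit combine a gene's spread between 2 pool pairs with a spread pooled over all genes. The pooled part weighs most, with 6.19 prior degrees of freedom against 1 residual. Neither measures the spread between the 12 sorted samples.

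The Ccr7 transcript gave less signal in the knock-out on both arrays. Its probe lies on chromosome 11 from 98960289 to 98960314 on mm8. The log2 ratio of knock-out over wild-type was -1.11 on array 1 and -0.74 on array 2, with a mean of -0.93 ± 0.15 (SE, n = 2), which is 1.90-fold lower. The limma adjusted p was 0.142, so Ccr7 was not past the threshold over all genes. The probe was well above background in the knock-out channel on both arrays. Whether it lies within the deleted part of the gene is not known here, so the residual signal does not measure how complete the deletion was. With an intensity trend and robust prior its adjusted p was 0.012, and it was 0.0129 without genes scaled up from the low-gain scan.

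Of 17684 genes tested, 18 differed between the genotypes at an adjusted p of 0.05, with 12 higher and 6 lower in the knock-out. All 18 went the same way on both arrays, and 14 of them had a proper gene symbol. The shared direction is no separate evidence, since opposite signs enlarge the residual and keep a gene from being called. With the sign of the second array turned, so that the fit followed the dye instead of the genotype, 0 genes passed. At an unadjusted p of 0.05, 441 passed against 1614 in the genotype direction, with 884 expected by chance. Ratios alike on both arrays enter the residual of the turned fit, so it is no null control. It does not show that dye effects were small: 50 genes were at least 2-fold different in opposite directions, against 20 in the same direction. Limma called 131 genes, 45 higher and 86 lower, when genes scaled up from the low-gain scan were left out, an alternative added after the data were examined. It called 0 genes on the deposited value table, with the smallest adjusted p at 0.0911, and 0 with the mean of all probes of a gene. The 18 calls therefore hold for the processing described and not for all of its alternatives.

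The largest rises were in genes of several kinds. Plekhh3 (chromosome 11, 100978794 to 100978853 on mm8) was 3.62-fold higher in the knock-out, with a log2 ratio of 1.86 ± 0.16 (SE, n = 2) and an adjusted p of 0.0244. Iigp1, an interferon-inducible GTPase, was 3.59-fold higher, with log2 ratios of 2.13 and 1.56 on the arrays. Jchain, the joining chain of secreted polymeric IgM and IgA, was 3.50-fold higher (log2 1.81 ± 0.13), and its other probe gave 2.00. Ffar2, a receptor for short-chain fatty acids, was 3.42-fold higher, with 1.78 and 1.76 on the arrays. Jchain and Ffar2 had the smallest adjusted p, 0.0177. The serine protease inhibitor genes Serpina3g and Serpina3f were 2.68-fold and 2.19-fold higher. Samsn1, an adaptor protein gene of lymphocytes, was 2.65-fold higher, and like Serpina3g it had a channel scaled up from the low-gain scan. The other rises were 2.53-fold for Parm1 and 2.35-fold for Nfil3, a basic leucine zipper transcription factor. The other probe of Parm1 gave a log2 ratio of only 0.49. Slpi, a secreted protease inhibitor, was at least 2-fold higher on both arrays (mean log2 1.28) but not past the threshold, with an adjusted p of 0.0718.

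Of the 18 genes, 6 fell. At an unadjusted p of 0.05 the balance was the other way, with 558 genes higher and 1056 lower, and 45 higher and 65 lower were at least 1.5-fold different on both arrays. Klf4, a Krüppel-like transcription factor, was 2.53-fold lower in the knock-out, with log2 ratios of -1.53 and -1.14 on the arrays (mean -1.34 ± 0.15 SE, n = 2). Hspa1a, a stress-inducible heat shock protein, was 2.47-fold lower (log2 -1.30 ± 0.15). Of its other 3 probes, the brightest gave -1.28 and the dimmer ones -0.68 and -0.17, and its near-identical copy Hspa1b can contribute to the signal. The histone gene H2bc4 was 2.22-fold lower, Wfdc21 2.21-fold and Galnt14, a glycosyltransferase, 2.19-fold. The adjusted p of each of these 5 genes was 0.049, close to the threshold, and 0 genes passed in this direction when both channels of both arrays had to be above background. Apol7c had a mean log2 ratio of -1.39 but an adjusted p of 0.0972, and its dimmer probe gave -0.57.

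**Figure D1:**
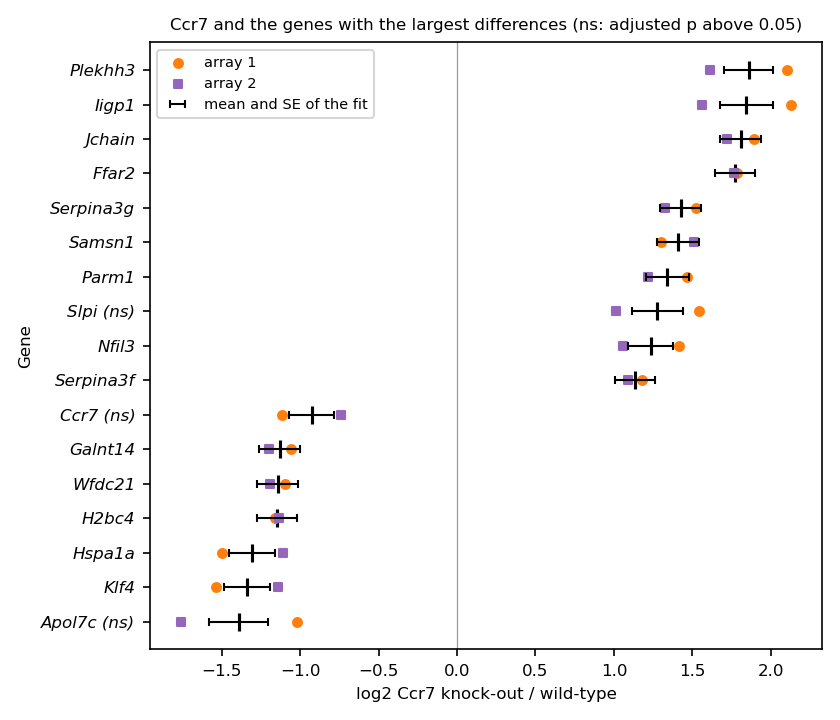
Log2 ratios of knock-out over wild-type (x axis) for Ccr7 and the genes named for their size (y axis), with array 1 as circles, array 2 as squares and the mean with the SE of the fit as bars. For each of the 17 genes shown, both arrays lie on the same side of 0, which the naming rule required of all but Ccr7.

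Over all genes the arrays shared only a small part of their ratios. Across genes, which are not independent replicates, Pearson's r between the oriented ratios was 0.098 and Spearman's rho 0.15. The relation depended on intensity. In each of the 9 dimmer deciles of genes by intensity r lay between 0.123 and 0.328, and in the brightest decile it was -0.498. On the deposited value table the brightest decile had r = 0.178. Of the 1769 genes in that decile, 1599 had a channel scaled up from the low-gain scan. Genes at least 2-fold different in the same direction on both arrays numbered 20, with 13 higher and 7 lower, whereas 50 were at least 2-fold different in opposite directions. All 50 had a scaled-up channel. This count depended on the processing: it was 3 on the deposited value table, 9 with separate channels, 21 with the scanner program's log ratio, 170 with median centring and 206 with no within-array normalization. Many MHC class II and B lineage genes are among those with a scaled-up channel, 10 of 13 and 21 of 23 members.

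**Figure D2:**
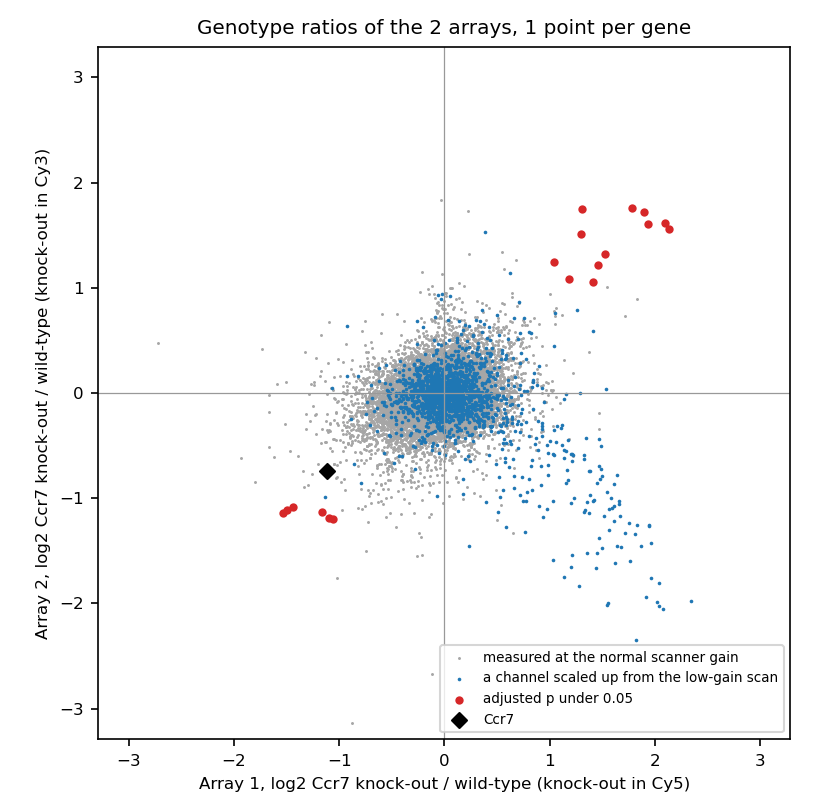
Log2 ratios of knock-out over wild-type on array 1 (x axis) and array 2 (y axis), 1 point per gene for 17684 genes, with genes that had a channel scaled up from the low-gain scan in blue, the 18 genes past the threshold in red and Ccr7 as a diamond. The 50 genes at least 2-fold different in opposite directions form the blue arm towards the lower right.

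Camera with a fixed correlation compares list members with other genes, so its p-values do not measure the spread between the 2 pool pairs. By fry 0 lists passed, with a lowest adjusted p of 0.201. The rises and falls of lists given here therefore describe these 2 arrays and are not established. Immediate early and stress genes were lower in the knock-out as a list. Of 19 members tested, 2 fell past the threshold over all genes, Klf4 and Hspa1a, and 8 fell when adjusted over the list alone: Klf4, Hspa1a, Fos, Jun, Dusp1, Fosb, Egr1 and Junb. The list's median log2 ratio was -0.31, 11 members were lower on both arrays and 0 higher on both. Camera gave an adjusted p of 6.02e-08, and the adjusted p was 0.636 with an estimated correlation. The AP-1 subunit genes Fos and Jun had log2 ratios of -1.32 and -0.82, and the phosphatase gene Dusp1 had -1.11.

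Among lists of B-cell activation and differentiation, the IL-4 response list rose, with a median log2 ratio of 0.12 and a camera adjusted p of 0.000456, or an adjusted p of 0.636 with an estimated correlation. Of its 16 members tested, Nfil3 passed over all genes. Adjusted over the list alone, 5 rose, among them Nfil3, Socs1, Xbp1 and Socs3, and 1 fell (Gfi1). The germinal centre list rose with a median of 0.35 and an adjusted p of 4.27e-05, or an adjusted p of 0.636 with an estimated correlation. None of its 14 members passed over all genes and 6 rose adjusted over the list alone. Rgs13, a regulator of G-protein signalling, had a log2 ratio of 0.89 ± 0.14 (SE, n = 2). Some genes, such as Fas, stand in several lists, so the lists are not independent. In the plasma cell list, 1 of 17 members rose over all genes, Jchain, and camera gave an adjusted p of 0.216. Adjusted over the list alone, 2 of its members rose (Jchain and Xbp1) and 1 fell (Fkbp11).

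The MHC class II list, the antigen-presenting molecules of B cells and their regulators, rose with a median log2 ratio of 0.34 and an adjusted p of 5.42e-06, or an adjusted p of 0.636 with an estimated correlation. None of its 13 members passed over all genes, 3 rose adjusted over the list alone (H2-DMa, H2-Aa and Ciita), and 7 were higher on both arrays. The other 6 had opposite signs on the arrays, and 10 of 13 had a scaled-up channel. Without scaled-up genes too few members were left to test the list. H2-Oa had a mean of 0.64 from 1.29 on array 1 and a value near 0 on array 2, while H2-DMa had 0.62 from 0.50 and 0.74. Cell cycle genes rose as a list, with a median of 0.14 and an adjusted p of 0.00371, or an adjusted p of 0.708 with an estimated correlation. None of 28 members passed, over all genes or over the list alone. The list's median was 0.23 on array 1 and 0.04 on array 2. Mki67 had a mean of 0.72 and Birc5 0.48. The unfolded protein response list rose with a median of 0.11 and an adjusted p of 0.0169, or an adjusted p of 0.708 with an estimated correlation. Of its 19 members, Xbp1 (0.70) rose adjusted over the list alone and Edem1 had 0.43. The list's median was 0.02 on array 1 and 0.13 on array 2. This call was lost in 6 of 14 other settings, with adjusted p from 0.0782 to 0.799, among them the deposited value table and median centring.

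Type I interferon response genes fell as a list, with a median log2 ratio of -0.19 and an adjusted p of 0.00348, or an adjusted p of 0.711 with an estimated correlation. None of 28 members passed. The fall came from array 1, where the list's median was -0.39, against 0.03 on array 2. Ifit1 had -1.59 and 0.08 on the arrays, and Rsad2 -1.11 and -0.35. The marginal zone and B1 list fell with a median of -0.16 and an adjusted p of 0.0228, or an adjusted p of 0.636 with an estimated correlation. None of 15 members passed over all genes. Adjusted over the list alone, 4 fell (Zbtb32, Spn, Cd300lf and Cd9) and 1 rose (S1pr3). Zbtb32 and Spn both had -0.68. Dimmer probes of Spn gave -0.31 and -0.18, the latter from 0.17 and -0.52 on the arrays.

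Other B-cell lists did not pass. The B lineage list had a median of 0.11 and an adjusted p of 0.55. Adjusted over the list alone, Cd72 rose and Pax5 fell. Pax5, the transcription factor of B-cell identity, had a log2 ratio of -0.82 by its bright probe and 0.01 by its dim probe, and Pou2af1 had 1.15 and -0.01 on the arrays. The activation and costimulation list had an adjusted p of 0.745. Adjusted over the list alone 3 of its 23 members rose, among them Cd83 (1.00), and 2 fell, among them the chemokine gene Ccl3 (-1.11). The NF-kB target list had an adjusted p of 0.55 with no member past the threshold, Rel at -0.74 and Traf1 at 0.29. The migration and homing list had an adjusted p of 0.858, with a camera direction upwards but a median of -0.03. Its members Rgs1 (-1.09) and Rgs2 (-1.06), regulators of G-protein signalling, fell adjusted over the list alone. Of the immunoglobulin list 5 genes were tested, with an adjusted p of 0.0675. The list passed upwards in 4 other settings, with adjusted p down to 0.000324, and not with an estimated correlation. Ighg had 0.38, and the brightest Ighm probe had 1.82 on array 1 and -2.35 on array 2.

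Markers of other cells the sort could hold were tested beside these. The T cell list fell with a median log2 ratio of -0.17 and an adjusted p of 0.00371, or an adjusted p of 0.636 with an estimated correlation. Of its 21 members none passed over all genes and 3 fell adjusted over the list alone (Thy1, Cd3d and Il7r). Ccl5 had -0.12 and -2.67 on the arrays, and Thy1 a mean of -0.78. The call was lost when both channels of both arrays had to be above background (adjusted p 0.177). The stroma and endothelium list rose with a median of 0.08 and an adjusted p of 0.041, or an adjusted p of 0.636 with an estimated correlation. This call was lost in 3 of 14 other settings, with adjusted p from 0.0543 to 0.147. None of its 16 members passed, and Col1a2 had 0.39. Cxcl12 was not well above background in the wild-type on either array and was at least 1.38-fold higher in the knock-out, with an adjusted p of 0.298. The myeloid and dendritic cell list (adjusted p 0.385, Adgre1 -0.71, S100a9 0.46) and the NK cell list (adjusted p 0.55, Klrd1 -0.57, Tbx21 0.57) did not pass here. Relative to all genes, both passed upwards with median centring and with no within-array normalization, with adjusted p of 0.00689 for the myeloid and dendritic cell list and 0.0228 for the NK cell list. Among 4 erythroid genes, too few for the list test, Hba-a1 had 0.48 and Hbb-bt -0.23. Of the sex-linked genes Xist alone was tested, with 0.25.

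**Figure D3:**
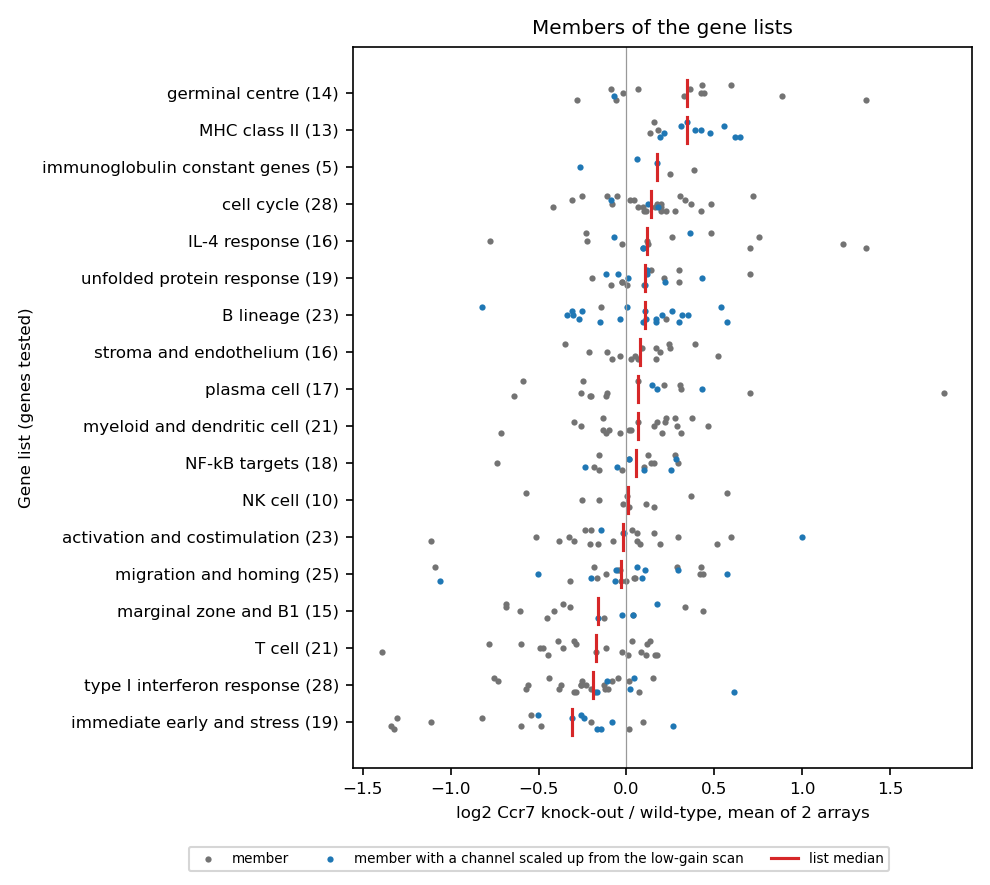
Mean log2 ratio of knock-out over wild-type (x axis) of each member of the 18 gene lists tested (y axis, number of genes tested in brackets), with the list median in red and members that had a channel scaled up from the low-gain scan in blue. Medians run from -0.31 for immediate early and stress genes to 0.35 for the germinal centre list.

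The name of the knock-out strain, B6.129P2(C)-Ccr7tm1Rfor/J, gives a donor strain other than B6, so neighbours of Ccr7 can carry donor sequence. Among 333 genes tested within 10 Mb of Ccr7 on chromosome 11, the median log2 ratio was 0.02. The p of limma's camera for this window was 0.266. Camera tests for a shared direction, so changes that go both ways can escape it. Of these genes 1 passed the threshold, Plekhh3 (Fisher's exact test, two-sided p = 0.29). Within 20 Mb, 3 of 607 genes passed, Plekhh3, Wfdc21 and 1 gene without a proper symbol (Fisher's exact test, two-sided p = 0.0224). In this window 81 of 607 genes (13.3%) were past an unadjusted p of 0.05, against 8.97% of other genes (Fisher's exact test, two-sided p = 0.00054). Nearer to Ccr7, where donor sequence is most likely, the shares were also above those of other genes, but the tests did not pass. Within 10 Mb the share was 37 of 333 genes (11.1%) against 9.08% (p = 0.211 by the same exact test). Within 5 Mb it was 25 of 253 (9.88%) against 9.11% (p = 0.66 by the same exact test). These windows hold fewer genes, so the tests do not exclude an excess there. The ratios of Plekhh3 and Wfdc21 cannot be assigned to the loss of Ccr7 rather than to donor sequence. The same holds for genes named above from the lists that lie in these windows and were not past the threshold. These are Tbx21 within 10 Mb, and Ccl3, Ccl5 and Birc5 within 20 Mb.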

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

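The setting without scaled-up genes was chosen after the result was seen. With 2 arrays the fit has 1 residual degree of freedom per gene beside the pooled prior, and dim probes are limited by signal over background. The count of 18 genes (12 higher, 6 lower) was 0 with no background subtraction, the scanner program's log ratio, no within-array normalization, the mean of probes, the deposited value table, and separate channels with no replicate block, 0 in each direction. It was 4 with median centring (3 higher and 1 lower), 9 with both channels of both arrays above background (0 lower), 78 with an intensity trend and robust prior (30 higher and 48 lower, with all 18 among them), and 131 without scaled-up genes (45 higher and 86 lower, 16 of the 18 among them). It was 4 with treat against 1.2-fold, and 12 were lower with all probes tested. The cause was not tested, except that left-out genes cannot be called. Counts with the other settings stayed within 1.5 times.

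The log2 ratio of Ccr7 ranged from -1.44 to -0.90 over 14 alternatives, with adjusted p from 0.012 to 1. It was -0.93 and past the threshold with the intensity trend and robust prior and without scaled-up genes. Array by array it was -1.11 and -0.74. The 20 genes 2-fold in the same direction became 99 with the scanner program's log ratio, 34 with no within-array normalization, 100 on the deposited value table, and 110 at 1.5-fold. On a single array 124 to 215 genes were 2-fold different.

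The correlation between arrays was 0.12 with an offset of 16, 0.214 with the scanner program's log ratio, -0.178 with median centring and with no within-array normalization, 0.0672 with no filter, 0.137 with all probes, 0.126 with the mean of probes, 0.244 on the deposited value table, 0.219 with separate channels, and 0.271 without scaled-up genes. Of 10 list shifts, 0 passed with an estimated correlation and 0 with fry. Single lists were lost in other settings: unfolded protein response in 6, stroma and endothelium in 3, and type I interferon, marginal zone and T cell in 1 each. Other lists gained a call: immunoglobulin in 4, and myeloid and NK cell in 2 settings that give the same list test. MHC class II was tested in 13 other settings and not 14, since too few members were left without scaled-up genes.

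Median centring moved the median of all genes to -0.17 and no normalization moved it to -0.39, so signs under them are relative to that shift. The median near Ccr7 was -0.14 and -0.36 under them and -0.0076 to 0.0282 on single arrays, and 3 genes passed within 20 Mb. Under median centring Xist was -0.032, above the median of all genes. The camera direction turned for B lineage (median -0.16), NF-kB targets (-0.23), immunoglobulin (-0.16) and migration (-0.21). With no normalization Traf1 (-0.22), Ighg (-0.12), Edem1 (-0.093) and Xist (-0.25) were below 0 but above the median of all genes. The camera direction again turned for B lineage (-0.38), NF-kB targets (-0.45), immunoglobulin (-0.38) and migration (-0.43). The medians of all lists that rose also went below 0 in some setting, with no turn of camera direction. The lowest values ran from -0.08 for stroma and endothelium to -0.40 for unfolded protein response. The camera direction of migration also turned with an offset of 16 (median -0.033), the log ratio (-0.039), the deposited table (-0.018), separate channels (-0.021) and fry (-0.033), and that of B lineage with the log ratio (-0.028) and the deposited table (-0.081). Without scaled-up genes another probe stood for Pax5 (0.01), Ighm (0.26) and Edem1 (-0.12). Type I interferon had 0.028 to -0.39 on single arrays. The separate channel fit with a dye term could not be fitted: with 0 residual degrees of freedom for the ratios the estimated correlation within spots reached 1.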

Other observations

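The tests of dye bias, of a dye effect at high intensity, of sorting and of myeloid cells, and the histone group, were chosen after the result was seen. Histone genes were noticed through H2bc4, and H2ac6 and H2ac8 had been seen too. Of the other 43 tested, 30 had a lower ratio on both arrays and 0 a higher one, against 30.0% and 24.2% of all genes, with a median log2 ratio of -0.29. Camera gave p = 2.5e-11 for these 43 genes, p = 0.284 with an estimated correlation (0.322), and fry p = 0.215, so a fall of the group is not established. H2ac6 had -0.91, H2ac8 -0.86 and H1f4 -0.57, and only H2bc4 passed the threshold. Many histone genes are near-identical copies whose probes can bind each other's RNA, so their values are not independent. The group also holds linker and variant histone genes, which were not alike: H1f0 had -0.015 and H2az2 0.085, whereas H1f4 fell.

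The brightest decile of genes had opposite ratios on the 2 arrays in the processing used here (r = -0.498) and not on the deposited value table (r = 0.178). Among the 1599 of them with a channel scaled up from the low-gain scan r was -0.508. Among the 170 without such a channel it was 0.251 (95% interval 0.105 to 0.387, with genes taken as independent). This is consistent with the scaled-up spots as the source. A dye effect left by loess stays open: the mean Cy5 over Cy3 log2 ratio of the brightest 5% of genes was 0.28 on array 1 and 0.17 on array 2. No biological explanation was tested.

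Immediate early and stress genes were lower in the knock-out as a list by camera, with 2 of 19 members past the threshold over all genes. The fall did not pass by camera with an estimated correlation (adjusted p 0.636) or by fry (adjusted p 0.201), so it is not established. The estimated correlation was -0.03, below the 0.01 of the main test, so correlation between members did not remove the call. With 1 residual degree of freedom that alternative could hardly pass any list: its lowest adjusted p over 18 lists was 0.636. The 2 SE ranges in this paragraph come from resampling list members, which are not independent. They do not measure the spread between the 2 arrays. The low-gain scan was argued against, since the 11 members with no scaled-up channel had a median of -0.60 (-1.15 to -0.05, 2 SE). Of these members, 8 were lower on both arrays and 0 higher on both. Dye bias of equal size on both arrays cancels in the mean over both orientations, so by design it cannot make up that mean. The median of that mean was -0.31 (-0.60 to -0.014, 2 SE), which only just leaves out 0, and 11 members were lower on both arrays and 0 higher. The same median made the list stand out, so its distance from 0 is no separate test of dye bias. Dye bias that differs between the arrays stays open. The median of the mean was the last of 3 readings, all made after the result was seen, and it replaced the first. The first, the median dye component, was -0.11 (-0.34 to 0.12), and the medians of the arrays were -0.41 (-0.92 to 0.097) and -0.44 (-0.66 to -0.21), so neither of these decides. A difference in sorting or dissociation may also have contributed, and 9 heat shock genes other than Hspa1a had a median of 0.013 (-0.16 to 0.19), which decides neither way. A difference in stimulation of the cells in the animal stays open as untested.

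Genes induced by interferon gamma tended to be higher in the knock-out, with 2 of 34 members past the threshold, both seen before the list was written. The type I interferon list fell on array 1 (median -0.39) and not on array 2 (0.03), with an adjusted p of 0.711 at an estimated correlation, so it gives no firm contrast. As a hypothesis, the B cells may have met more interferon gamma. The 23 members whose values had not been seen when the list was written had a median log2 ratio of 0.16 with 12 higher and 2 lower on both arrays. That median turned to -0.12 with median centring and -0.34 with no normalization, but relative to all genes it stayed above 0, at 0.06 under both. Camera gave p = 8.15e-05 for these members, p = 0.15 with an estimated correlation, and fry p = 0.107, so a rise of the group is not established. Dye bias of equal size on both arrays cancels in the mean over both orientations, so by design it cannot make up the genotype median. The 23 members not seen before had a median dye component of -0.012 against a genotype median of 0.16. Over all 34 members these medians were 0.0087 and 0.30, but the 34 include members whose values had been seen. A small dye component cannot exclude dye bias that differs between the arrays, which stays open. More macrophages or dendritic cells in the sort stay open: the myeloid list had a median of 0.064 and did not pass by camera (adjusted p 0.385). Relative to all genes it passed upwards with median centring and with no within-array normalization (camera adjusted p 0.00689 in each). These 2 settings are the same list test and leave a trend with intensity in the ratios, so they do not decide. Lyz2 had a log2 ratio of 0.31 ± 0.36 and Tyrobp -0.30 ± 0.13 (SE, n = 2).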
